A study of Mus musculus with 34 samples.

How the data were processed

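The values analysed were expected counts per gene, deposited by the authors as 1 table with 34 columns, 1 per library, and 0 columns were left unused. Per the labels' protocols, total RNA was prepared with a kit that removes ribosomal RNA and keeps strand information by dUTP, and was sequenced in pairs on an Illumina instrument. Per the submitters' processing notes, bcl2fastq 2.20, FastQC, STAR, RSEM and limma were used, without a statement of which step each served, and the builds mm10 and GRCm38 are named. The annotation release, any filter and the strand setting of the counting are not stated. The values themselves were whole in 83.7 to 90.8% of cases per library and carried decimals otherwise, as the expected counts of RSEM do. No scaling between samples was found in them. Reads shared between near-identical genes, such as histone genes, are divided between the copies by such estimates, so single members of such families are uncertain, as are genes that overlap an antisense partner.

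Columns were matched to samples by group and number. For CD28 KO at day 3 the sample titles and the columns carry different numbers, so these 2 columns were matched to the group and not to single samples. The table held 48526 genes, of which 48144 (99.2%) matched GENCODE M21 (GRCm38) by Ensembl identifier, 40692 of them in the same version. Where genes shared a symbol, the symbol stayed with the gene of the highest mean, and 71 others kept their identifier. Coordinates come from that annotation.

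Expected counts were rounded and fitted with edgeR 4.0.16 in R 4.3.3, using quasi-likelihood F tests on a model with 1 mean per group over all 34 libraries, TMM scaling and the default filter on low counts. This left 18292 genes, which held at least 99.9% of the counts of every library. TMM factors ranged from 0.83 to 1.11, and were 0.83 to 0.86 in the unstimulated libraries. The biological coefficient of variation from the common dispersion, 1 value for all genes, was 0.16. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05, and the standard error of a log2 fold change was its size divided by the square root of F. Contrasts set each genotype against WT of the same day and against unstimulated WT, DKI against CD28 KO, CD28 AYAA against CD28 Y170F, and the day 3 effect of each genotype against its day 1 effect. CPM values use TMM library sizes, except the summed levels of cell markers and the values of Ighm, which use total counts without TMM factors. Errors beside means are SDs. Genes at 0 in a group are described by their counts without a fold change. limma 3.58.1 and DESeq2 1.42.0 served as alternatives, and tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

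The design, the alternatives and the rule for named genes were fixed before the data were examined. Srrt, Cd28 and Pkm were always named. In each comparison with WT of the same day, and of stimulated with unstimulated WT, up to 6 genes per direction with the largest log2 fold change were eligible, and up to 3 in comparisons of alleles and in interactions. They had to have an adjusted p under 0.05, a mean log2 CPM of at least 3 and, except in interactions, CPM values that do not overlap between the groups. Predicted genes with numbered names, mitochondrial and ribosomal protein genes, antigen receptor segments, Xist and Y-linked genes were left out of this ranking. From each list described, up to 4 members with the smallest p were eligible, with any the series title concerns. Other named genes are said to be chosen after their values were seen.

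Alternatives were RLE size factors, DESeq2, limma-voom, no filter on low counts, a fit to only the groups compared, the replicate number as a block, a minimum of 3 for the mean log2 CPM in correlations, and each library left out in turn. Depth batch as a term, sex as a term and protein-coding genes alone were added later. Library depth ranged from 8.3 to 47.8 M, and 8 libraries under 12 M were treated as a batch, which the labels do not name. Comparisons that share WT libraries were set beside 50 simulations of groups without an effect.

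A set of 28 gene lists, also written before, was tested with camera in limma at a preset correlation of 0.01 between genes, and again with the correlation estimated from the data. Benjamini-Hochberg adjustment ran over the 28 lists of a comparison. At the preset correlation 450 of 868 list tests passed, and 45 with the estimated correlation, so those described as lost with an estimated correlation rest on the preset one. Counts of members that rose or fell use the adjustment over all genes, and those adjusted over the list alone use only the members of the list.

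Samples of CD28 AYAA and CD28 Y170F carry the same replicate numbers. At day 1 the deviations from the group means correlated at 0.29, 0.32 and 0.52 for samples of the same number, so the numbers paired the samples, a reading that rests on these correlations and not on the labels. At day 3 they correlated at -0.27, 0.07 and -0.12 and did not pair them. The test of 29 pairs of replicates on genes with more than 100 counts gave a mean chi-square of 2.21 to 5.54 in DKI and 5.45 to 92.7 in the other groups, so no pair agreed within sampling noise alone.

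Each step was first run on counts simulated from the real means, library sizes and spread with a known set of changed genes. With 18022 genes in the simulation of Ars2 KO against WT at day 1, 26.2% of changes of 1.5-fold, 49.2% of 2-fold and 72.7% of 4-fold were recovered, and 9.3% of 107 calls were false. For CD28 KO at day 1 (18010 genes) recovery was 19.4, 50.7 and 71.9%, with 5.1% false. For CD28 Y170F at day 3 (18059 genes) it was 27.3, 44.8 and 71.2%, with 2.1% false. For CD28 AYAA against CD28 Y170F at day 1 (18074 genes) it was 28.8, 57.6 and 79.4%, with 6.1% false. For WT at day 1 against day 0 (18136 genes) it was 23.9, 50.7 and 77.3%, with 12.2% false, above the nominal rate. The false shares of 9.3, 6.1 and 5.1% also lay above it, and only that of CD28 Y170F lay below. No call had the wrong sign, and 0 of 28 unchanged lists were called in the simulation of CD28 KO. Genes were drawn independently there, so that result does not check list calls at the preset correlation where members are correlated. The rates of recovered and false calls hold only for the simulated spread. Between real replicates of CD28 Y170F at day 3 the mean chi-square was 69.5 and 92.7 for pairs with library 1. It was 8.87 for the remaining pair. The rates do not check comparisons whose libraries vary more, or less evenly, than those simulated.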

Results

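Total RNA depleted of ribosomal RNA was sequenced from mouse splenic T cells before and after stimulation with antibodies to CD3 and CD28 and added IL-2. CD28 is the costimulatory receptor that T cells need, beside the antigen receptor, for full activation. The series title names CD28, the cap-binding complex with its partner ARS2, splicing of Pkm and CD8 T cell glycolysis as its subject. ARS2 is encoded by Srrt and binds capped transcripts with the nuclear cap-binding complex, and Pkm encodes pyruvate kinase, whose alternative exons give separate enzyme forms. The 34 libraries fell into 13 groups. WT cells were sampled unstimulated at day 0 and after 24 h (day 1) and 72 h (day 3), with 2 libraries each. Libraries labelled CD28 KO numbered 2 per day at days 1 and 3. Ars2 KO, DKI, CD28 AYAA and CD28 Y170F had 3 libraries per day at days 1 and 3. AYAA alters a proline motif and Y170F a tyrosine motif of the CD28 tail. The labels do not say which changes DKI carries. Replicates are biological per the labels, so the p-values measure the spread between samples, estimated over all groups together.

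Total expected counts ranged from 8.3 to 47.8 M (mega, the SI prefix) per library. The 2 unstimulated libraries held 44.0 and 47.8 M. A batch of 8 libraries held under 12 M, namely all 6 DKI libraries with 8.3 to 10.6 M, WT number 4 at day 1 with 10.4 M and WT number 4 at day 3 with 10.1 M. WT number 1 held 26.4 M at day 1 and 25.2 M at day 3. Ars2 KO libraries held 23.7 to 32.0 M at day 1 and 26.6 to 30.3 M at day 3. CD28 AYAA libraries held 19.0 to 21.4 and 22.3 to 27.7 M, and CD28 Y170F libraries 18.6 to 21.8 and 22.3 to 25.2 M. Libraries labelled CD28 KO held 15.7 to 18.9 and 23.8 to 27.3 M. DKI therefore shares its depth batch with WT number 4, and every other mutant shares it with WT number 1, so comparisons with WT are also given against that WT library alone. Sex, read from Xist and Y-linked genes, was female in both unstimulated libraries, male in all stimulated WT and DKI libraries, and mixed in the other groups.

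Srrt (ENSMUSG00000037364.11, GRCm38 chromosome 5, 137295704 to 137307674) was the gene targeted in Ars2 KO. It stood at 33.8, 64.8 and 33.5 CPM (counts per M counts) in the Ars2 KO libraries at day 1, against 244 and 131 in WT. The log2 fold change was -2.09 (SE 0.23, adjusted p = 1.9e-05). At day 3 the Ars2 KO libraries held 108, 146 and 105 CPM against 245 and 145 in WT, a log2 fold change of -0.71 (SE 0.23, adjusted p = 0.042). Against WT number 1 alone the Srrt values were -2.51 (SE 0.24) and -1.04 (SE 0.26), and against WT number 4 alone -1.55 (adjusted p = 0.0014) and -0.3 (adjusted p = 0.54), so the day 3 call rests on WT number 1. In the other groups Srrt averaged 151 to 250 CPM, and no other genotype differed in it from the mean of both WT libraries of the same day. Libraries labelled CD28 KO were lower against WT number 1 alone at day 1 (log2 fold change -0.69, SE 0.27, adjusted p = 0.042).

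Cd28 (ENSMUSG00000026012.2, GRCm38 chromosome 1, 60716800 to 60773359) averaged 192 ± 7.75 CPM (SD, n = 2) in unstimulated WT, 399 ± 17.2 at day 1 and 531 ± 79.9 at day 3. Libraries labelled CD28 KO held 479 ± 3.84 CPM at day 1, which was not lower than WT (log2 fold change 0.26, SE 0.18, adjusted p = 0.24), and 213 ± 1.19 CPM at day 3 (log2 fold change -1.32, SE 0.18, adjusted p = 1.6e-05). The gene-level count covers every exon and does not check the knockout label, nor does it check the point changes of the other alleles. Cd28 also fell at day 3 in DKI, with a log2 fold change of -0.91 (adjusted p = 1.9e-04). The day 3 log2 fold changes were -0.78 in CD28 AYAA (adjusted p = 9.1e-04) and -0.74 in Ars2 KO (adjusted p = 0.0032). In Ars2 KO the value against WT number 1 alone was -0.57 and did not pass (adjusted p = 0.098). CD28 Y170F held 365 ± 8.69 CPM at day 1 and 545 ± 67.6 at day 3, and did not differ from WT.

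Pkm (ENSMUSG00000032294.16, GRCm38 chromosome 9, 59656368 to 59679375) rose on stimulation of WT cells from 354 ± 5.11 CPM (SD, n = 2) to 765 ± 173 at day 1 and 1300 ± 676 at day 3. The log2 fold changes were 1.11 (SE 0.32, adjusted p = 0.0051) and 1.88 (SE 0.33, adjusted p = 3.2e-05). At day 1 it stood at 244 ± 15.4 CPM in libraries labelled CD28 KO (n = 2), a log2 fold change of -1.65 against WT (SE 0.32, adjusted p = 2.1e-04). DKI held 365 ± 14.3 CPM (n = 3), a log2 fold change of -1.07 (SE 0.29, adjusted p = 0.0079). Against the WT library of the same depth batch the first became -1.86 (SE 0.37, adjusted p = 3.0e-04), while DKI became -0.77 and did not pass (adjusted p = 0.23). Pkm did not pass in CD28 AYAA (507 ± 13 CPM, adjusted p = 0.22), CD28 Y170F (757 ± 50.6 CPM, adjusted p = 1) or Ars2 KO (742 ± 120 CPM, adjusted p = 0.99) at day 1. At day 3 no genotype differed from WT in Pkm, with means of 874 to 1080 CPM. These counts sum all transcripts of the gene and cannot tell its splice forms apart.

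**Figure D1:**
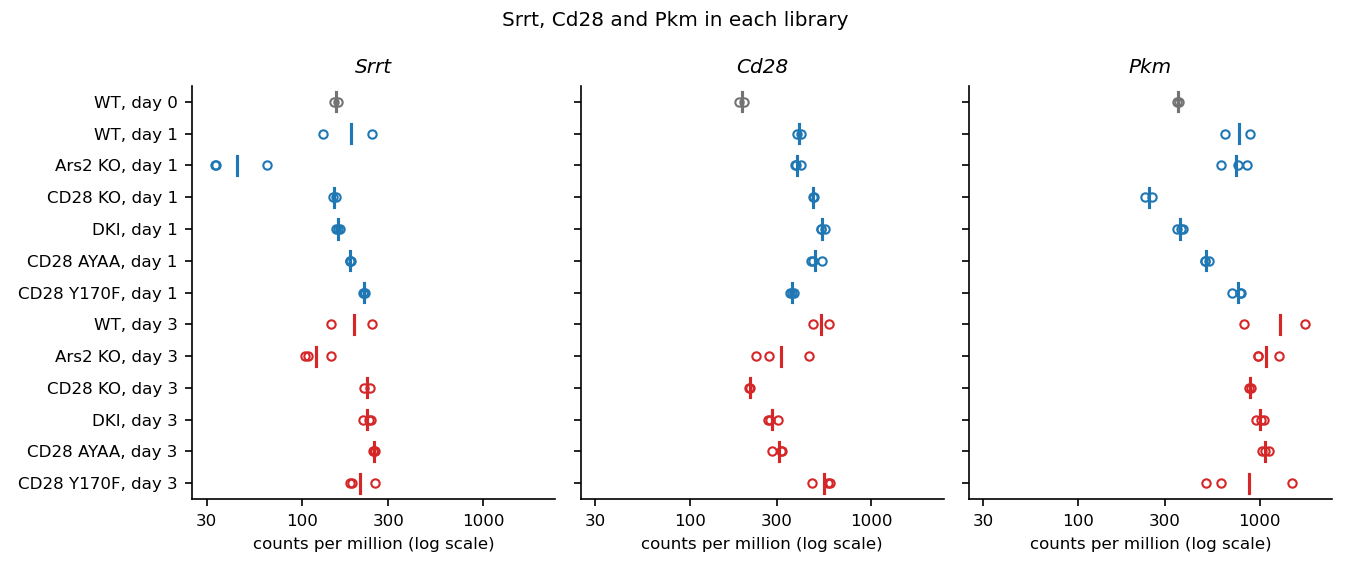
Srrt, Cd28 and Pkm in counts per M on a log axis, with 1 circle per library and a bar at each group mean. Srrt is lower in the Ars2 KO libraries at day 1 (33.5 to 64.8) than in WT (131 and 244), and Cd28 is not lower in libraries labelled CD28 KO at day 1.

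WT cells at days 1 and 3 were compared with unstimulated WT cells to describe the response to stimulation (n = 2 in each group). At day 1, 9390 of 18292 genes changed (4420 higher and 4970 lower), and at day 3 the number was 9237 (4298 higher and 4939 lower). The cytokine gene Lif had a log2 fold change of 7.42 (SE 0.9, adjusted p = 2.5e-07) at day 1. Il2ra, which encodes a chain of the IL-2 receptor, went from 28.7 ± 2.45 to 715 ± 100 CPM (log2 fold change 4.64, SE 0.3). Gzmb, encoding the cytotoxic protease granzyme B, held 8.65 ± 1.75 CPM before stimulation and 618 ± 169 CPM at day 3 (log2 fold change 6.16, SE 0.81, adjusted p = 5.7e-07). Among genes eligible for naming, Dtx1 had the lowest log2 fold change at day 3, at -7.53 (SE 0.39).

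Of 21 glycolysis genes, 13 rose and 1 fell in WT at day 1, and the same numbers held when adjusted over the list alone. Gapdh rose by 2.16 (SE 0.27) and Pgk1 by 1.87 (SE 0.33) on the log2 scale, while the glucose transporter gene Slc2a3 fell 2-fold, from 69.1 to 34.5 CPM. The list test gave adjusted p = 0.012, and adjusted p = 0.67 with an estimated correlation. At day 3, 15 rose and 0 fell, with 18 rising when adjusted over the list alone, led by Gapdh at 2.94 (SE 0.28). That list test gave adjusted p = 1.2e-05, and adjusted p = 0.44 with an estimated correlation. Of 34 cell cycle genes, 30 rose and 0 fell at day 1 and 34 rose at day 3, among them Aurkb at 3.35 and Top2a at 3.27. The test gave adjusted p = 1.1e-10 at day 1, and adjusted p = 0.39 with an estimated correlation. At day 3 the values were adjusted p = 3.5e-20 and adjusted p = 0.17 with an estimated correlation. Early activation genes rose in 19 cases and fell in 1 of 26 at day 1 (adjusted p = 2.8e-08, and adjusted p = 0.024 with an estimated correlation). Of 33 splicing regulators, 23 rose and 5 fell at day 1, with 24 rising when adjusted over the list alone, among them Hnrnpa1 at 2.13 (SE 0.15). Among 20 genes of the cap-binding complex and ARS2 partners, 12 rose and 0 fell, including Ncbp2 at 1.09 (SE 0.15). The tests of these last lists gave adjusted p = 4.0e-05 and 0.001, and adjusted p = 0.39 with an estimated correlation for each.

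Markers of other cells and RNA composition differed along with stimulation. All 17 myeloid and all 15 B cell markers fell at days 1 and 3. Mitochondrial ribosomal RNA made up 17.2 to 17.5% of counts in the unstimulated libraries and at most 0.18% in the 32 stimulated ones. Small noncoding RNA made up 14.8 to 15.3% against 3.5 to 7.3%, and Snord17, a small nucleolar RNA, fell from 652 ± 47.5 to 14.6 ± 1.9 CPM at day 1. The comparison with day 0 also sets male libraries against female ones.

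Each mutant was compared with unstimulated WT as well, as the design text states. The number of changed genes at day 1 was 9810 in Ars2 KO, 9546 in libraries labelled CD28 KO, 8990 in DKI, 9148 in CD28 AYAA and 10001 in CD28 Y170F. At day 3 these numbers were 10391, 9532, 10627, 11004 and 9833 in that order. Against day 0, 33 of 34 cell cycle genes rose at day 1 in Ars2 KO and 30 in CD28 Y170F, while 2 rose and 24 fell in libraries labelled CD28 KO and 5 rose and 14 fell in DKI. Of 21 glycolysis genes, 13 rose and 1 fell at day 1 in both Ars2 KO and CD28 Y170F, 10 rose and 2 fell in CD28 AYAA, 4 rose and 3 fell in DKI, and 1 rose and 4 fell in libraries labelled CD28 KO. By day 3 cell cycle genes had risen in 33 or 34 of 34 cases in every genotype, and glycolysis genes in 14 to 16 of 21.

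Ars2 KO was compared with WT on each day to ask what loss of Srrt changes in stimulated cells (n = 3 and 2). At day 1, 73 genes changed (42 higher and 31 lower), and 33 (11 higher and 22 lower) against WT number 1 alone, with 23 genes called in both. A fit to these groups alone called 4 genes. Tkfc, encoding a triokinase, rose from 5.97 ± 0.806 to 15.5 ± 0.72 CPM (log2 fold change 1.39, SE 0.17, adjusted p = 6.7e-05). Hist1h4i rose by 1.28 (SE 0.19, adjusted p = 0.0012) and Hist1h2bf by 1.48 (SE 0.26, adjusted p = 0.0065), although histone genes resemble each other closely enough for reads to be shared between copies. Among genes eligible for naming, the lowest values after Srrt were those of Rnf157 (-1.41, SE 0.23) and Ly6c1 (-1.4, SE 0.31), a surface marker of some memory T cells. Of 64 replication-dependent histone genes, 3 rose and 0 fell, with 14 rising when adjusted over the list alone. The list test gave adjusted p = 3.0e-25, and adjusted p = 0.62 with an estimated correlation. Against WT number 1 alone 0 of these genes passed by edgeR, and their median log2 fold change was -0.07 where it had been 0.47. No glycolysis gene of 21 changed by edgeR, and the list did not pass (adjusted p = 0.35). Without Ars2 KO number 1 the count was 28, and without WT number 1 it was 201.

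At day 3 the count in Ars2 KO was 2353 (1207 higher and 1146 lower). Against WT number 1 alone it was 700 (304 higher and 396 lower), of which 628 were among the 2353. A fit to these groups alone called 0 genes at day 3 by edgeR, with 2382 at an unadjusted p under 0.05, while on all libraries DESeq2 called 2739 and limma-voom 2071. Lta, encoding lymphotoxin alpha, rose from 8.47 ± 5.79 to 71.8 ± 37.2 CPM (log2 fold change 2.99, SE 0.4, adjusted p = 4.9e-05). Lif had a log2 fold change of 2.82 (SE 0.66), Lrrc32 of 2.24 (SE 0.35) and Cish, a target of IL-2 signalling, of 1.99 (SE 0.33). Ly6c1 (-2.07, SE 0.32) and Dapl1 (-1.8, SE 0.29) were lower.

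Ribosome biogenesis genes rose in 21 and fell in 0 of 29 cases in Ars2 KO at day 3, with 24 rising when adjusted over the list alone. Gnl3 had a log2 fold change of 1.51 (SE 0.3) and Ltv1 of 1.25 (SE 0.22). The list test gave adjusted p = 2.5e-16, and adjusted p = 0.23 with an estimated correlation. Cytokine genes rose in 6 and fell in 0 of 17 cases, with 8 rising when adjusted over the list alone (adjusted p = 3.5e-06, and adjusted p = 0.011 with an estimated correlation). Of 23 genes of naive and quiescent T cells, 1 rose and 12 fell, with 18 falling when adjusted over the list alone, among them Tcf7 at -1.05 (SE 0.21) and Klf3 at -1.21 (SE 0.25). That test gave adjusted p = 6.6e-11, and adjusted p = 0.23 with an estimated correlation. Glycolysis genes fell in 2 and rose in 0 of 21 cases, Aldoc (-1.87, SE 0.44) and Slc2a3 (-0.58, SE 0.16) being those. The list test gave adjusted p = 0.022, and adjusted p = 0.62 with an estimated correlation. Of 17 myeloid markers 7 rose and 0 fell, with a median log2 fold change of 2.26. Against WT number 1 alone none passed by edgeR, with a median of 2.07, and their summed level was 104, 72.8 and 75.2 CPM against 66.8 and 92.7 in WT. Against WT number 1 alone 1 ribosome biogenesis gene rose (median log2 fold change 0.68, from 0.94 with both WT libraries), 3 cytokine genes rose and 4 naive and quiescent genes fell (median -0.44, from -0.67). Glycolysis genes that fell numbered 7 there, with a median of -0.72. Without Ars2 KO number 3 the count of changed genes was 3581.

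Libraries labelled CD28 KO were compared with WT to ask how cells with that label respond (n = 2 and 2). At day 1, 7922 genes changed (3397 higher and 4525 lower), and 7423 against WT number 1 alone, with 6865 called in both. Lif fell from 107 ± 39 to 1.62 ± 0.826 CPM (log2 fold change -6.02, SE 0.86, adjusted p = 4.7e-06). Hk2, encoding the hexokinase that commits glucose to glycolysis, fell from 77 ± 24.7 to 4.78 ± 2.04 CPM (16-fold lower, SE 0.68 on the log2 scale, adjusted p = 4.1e-05). Il12rb2 (-5.06, SE 0.36) and Irf8 (-3.97, SE 0.33) were lower as well. Ctse, encoding cathepsin E on chromosome 1, rose from 6.13 ± 0.976 to 278 ± 13.6 CPM (log2 fold change 5.53, SE 0.25, adjusted p = 5.7e-14), and Pik3ip1 rose by 2.09 (SE 0.4). Without WT number 1 the count was 4868.

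Of 34 cell cycle genes, 33 fell and 1 rose at day 1 in libraries labelled CD28 KO, with Aurkb at -3.25 (SE 0.28) and Top2a at -3.17 (SE 0.28). The test gave adjusted p = 1.8e-32, and adjusted p = 0.14 with an estimated correlation. All 32 oxidative phosphorylation genes fell (adjusted p = 1.5e-18, and adjusted p = 0.23 with an estimated correlation), as did 26 of 29 ribosome biogenesis genes (adjusted p = 3.2e-12, and adjusted p = 0.3 with an estimated correlation). Adjusted over the list alone, these numbers were 32 and 28. Glycolysis genes fell in 13 and rose in 1 of 21 cases, and in 14 and 2 when adjusted over the list alone. Gapdh was at -2.09 (SE 0.27), Slc16a1 at -2.01 (SE 0.3) and Ldha at -1.97 (SE 0.34). The glycolysis test gave adjusted p = 8.8e-04, and adjusted p = 0.46 with an estimated correlation. Early activation genes fell in 18 and rose in 1 of 26 cases, among them Irf4 at -3.87 (SE 0.29). That test held with an estimated correlation (adjusted p = 1.3e-10 and adjusted p = 0.022). Splicing regulators fell in 21 and rose in 6 of 33 cases, with Hnrnpa1 at -1.39 (SE 0.15), and the test gave adjusted p = 0.0032, and adjusted p = 0.43 with an estimated correlation. B cell markers rose in 10 and fell in 0 of 15 cases, and apart from Ighm, chosen after its values were seen, their summed levels were 198 and 131 CPM against 73.5 and 22.5 in WT. With WT number 1 as the only control 33 cell cycle, 32 oxidative phosphorylation, 26 ribosome biogenesis, 13 glycolysis and 15 early activation genes fell.

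At day 3, libraries labelled CD28 KO differed from WT in 3664 genes (1568 higher and 2096 lower), and in 1977 against WT number 1 alone, with 1839 called in both. A fit to these groups alone called 2254, and without the library in column 2 the count was 1752. Ctla4, encoding an inhibitory receptor that shares the ligands of CD28, fell from 204 ± 3.57 to 10.6 ± 4.46 CPM (log2 fold change -4.26, SE 0.49, adjusted p = 2.4e-06). It lies 0.2 Mb from Cd28, and in CD28 Y170F its log2 fold changes were 0.52 at day 1 (adjusted p = 1) and 0.38 at day 3 (adjusted p = 0.92). Scd2, a fatty acid desaturase gene, was at -2.96 (SE 0.47) and Slc16a3, a lactate transporter gene, at -2.73 (SE 0.62). Ctse stayed higher (5.05, SE 0.25), and Lta (3.08, SE 0.42) and Lif (2.57, SE 0.68) were above WT, opposite to day 1 for Lif. Ribosome biogenesis genes rose in 22 and fell in 0 of 29 cases, with 25 and 1 when adjusted over the list alone (adjusted p = 3.0e-14, and adjusted p = 0.52 with an estimated correlation). Cytokine genes rose in 9 and fell in 0 of 17 cases (adjusted p = 8.9e-05, and adjusted p = 0.033 with an estimated correlation). Glycolysis genes fell in 6 and rose in 0 of 21 cases, 8 falling when adjusted over the list alone, with Aldoc at -3.61 (SE 0.55) and Slc2a3 at -1.01 (SE 0.18). That test gave adjusted p = 0.0013, and adjusted p = 0.7 with an estimated correlation. In the comparison with WT number 1 alone 9 ribosome biogenesis and 4 cytokine genes rose, and 11 glycolysis genes fell.

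DKI was compared with WT in the same way (n = 3 and 2). At day 1, 4765 genes changed (1884 higher and 2881 lower), but 671 (176 higher and 495 lower) against WT number 4 alone, the WT library of its depth batch. Of these 671, 658 were among the 4765. Gzmb fell from 293 ± 109 to 33 ± 9.82 CPM (log2 fold change -3.15, SE 0.61, adjusted p = 6.0e-04) and Ccnb1, a mitotic cyclin gene, was at -2.99 (SE 0.34). Ephx1 rose by 2.3 (SE 0.3, adjusted p = 5.0e-06) and Sytl2 by 1.68 (SE 0.3). Cell cycle genes fell in 33 and rose in 1 of 34 cases, with Ccna2 at -2.88 (SE 0.28), and the test gave adjusted p = 2.8e-47, and adjusted p = 0.059 with an estimated correlation. Replication-dependent histone genes fell in 57 and rose in 1 of 64 cases (58 and 2 when adjusted over the list alone), and the test gave adjusted p = 4.6e-60, and adjusted p = 0.059 with an estimated correlation. Glycolysis genes fell in 10 and rose in 0 of 21 cases, and in 14 and 1 when adjusted over the list alone, with Slc16a1 at -1.29 (SE 0.27) and Gapdh at -0.99 (SE 0.23). That test gave adjusted p = 8.1e-04, and adjusted p = 0.52 with an estimated correlation. Against WT number 4 alone 0 glycolysis genes passed by edgeR, and their median log2 fold change went from -0.75 to -0.55. There 25 cell cycle, 39 histone and 6 early activation genes fell.

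At day 3, DKI differed from WT in 4279 genes (1877 higher and 2402 lower), in 3496 against WT number 4 alone (3043 called in both), and in 2132 without that library. Lta rose from 8.47 ± 5.79 to 84.3 ± 5.3 CPM (log2 fold change 3.23, SE 0.41, adjusted p = 5.1e-06), and Lif by 3.15 (SE 0.67). Lrrc32, which anchors latent TGF-beta at the cell surface, rose by 3.06 (SE 0.36). Ctla4 (-2.38, SE 0.39) and Ly6c1 (-2.63, SE 0.36) were lower. Ribosome biogenesis genes rose in 26 and fell in 0 of 29 cases, with Gnl3 at 1.97 (SE 0.3) and Wdr43 at 1.27 (SE 0.19), and the test gave adjusted p = 4.6e-23, and adjusted p = 0.24 with an estimated correlation. Cytokine genes rose in 7 and fell in 0 of 17 cases, with 8 rising when adjusted over the list alone (adjusted p = 3.7e-06, and adjusted p = 0.0077 with an estimated correlation). Naive and quiescent T cell genes fell in 16 and rose in 1 of 23 cases, with 21 falling when adjusted over the list alone, among them Tcf7 at -1.42 (SE 0.21). That test gave adjusted p = 3.1e-08, and adjusted p = 0.6 with an estimated correlation. Cell cycle genes (2 rose and 1 fell of 34) and glycolysis genes (1 rose and 4 fell of 21) did not pass as lists, with adjusted p = 0.63 and 0.14. The median glycolysis log2 fold change was -0.3, and 0.28 against WT number 4 alone. Set against WT number 1 alone, day 3 medians were -0.72 in Ars2 KO, -0.99 in libraries labelled CD28 KO, -0.68 in CD28 AYAA and -1.02 in CD28 Y170F. Lower glycolysis genes at day 3 are thus not separated from the choice of WT library. Against WT number 4 alone 26 ribosome biogenesis and 6 cytokine genes rose, and 20 naive and quiescent genes fell.

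CD28 AYAA was compared with WT to ask what the proline motif contributes (n = 3 and 2). At day 1, 661 genes changed (295 higher and 366 lower), and 1146 (302 higher and 844 lower) against WT number 1 alone, with 478 called in both. Without WT number 1 the count was 67, and with depth batch as a term it was 2248. Irf8 fell from 206 ± 33.5 to 40.2 ± 2.61 CPM (log2 fold change -2.36, SE 0.26, adjusted p = 9.7e-06). Tbx21, encoding the transcription factor T-bet, was at -2.1 (SE 0.24), Lif at -2.04 (SE 0.57) and Lta at -1.9 (SE 0.34). Ephx1 rose by 2.04 (SE 0.3, adjusted p = 3.5e-04), as in DKI. Early activation genes fell in 8 and rose in 1 of 26 cases, with 12 and 1 when adjusted over the list alone, among them Nr4a3 at -1.79 (SE 0.27). That test gave adjusted p = 4.9e-11, and adjusted p = 0.017 with an estimated correlation. Cytokine genes fell in 4 and rose in 0 of 17 cases, 5 when adjusted over the list alone (adjusted p = 1.5e-04, and adjusted p = 0.021 with an estimated correlation). Cell cycle genes fell in 10 and rose in 0 of 34 cases, 29 when adjusted over the list alone, with Ccnb1 at -1.32 (SE 0.3). The test gave adjusted p = 1.1e-15, and adjusted p = 0.24 with an estimated correlation. No glycolysis gene of 21 passed by edgeR, and Hk2 stood at -1.67 (SE 0.52, adjusted p = 0.069). The glycolysis list was lower with adjusted p = 0.0057, and adjusted p = 0.53 with an estimated correlation. When set against WT number 1 alone, 24 cell cycle, 8 early activation and 4 cytokine genes fell, as did 1 glycolysis gene.

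At day 3, CD28 AYAA differed from WT in 3966 genes (1894 higher and 2072 lower), and in 1316 (513 higher and 803 lower) against WT number 1 alone, with 1263 called in both. Lif rose from 12.4 ± 14.5 to 162 ± 2.7 CPM (log2 fold change 3.6, SE 0.68, adjusted p = 5.1e-04), Lta by 3.34 (SE 0.41) and Lrrc32 by 2.99 (SE 0.36). Ctla4 was at -2.13 (SE 0.38) and Ly6c1 at -2.56 (SE 0.33). Ribosome biogenesis genes rose in 26 and fell in 0 of 29 cases, with Nle1 at 1.44 (SE 0.22), and the test gave adjusted p = 2.1e-23, and adjusted p = 0.23 with an estimated correlation. Naive and quiescent T cell genes fell in 19 and rose in 1 of 23 cases, with 21 falling when adjusted over the list alone. That test gave adjusted p = 1.5e-11, and adjusted p = 0.34 with an estimated correlation. Cytokine genes rose in 7 and fell in 0 of 17 cases, 8 when adjusted over the list alone (adjusted p = 1.6e-06, and adjusted p = 0.0048 with an estimated correlation). Glycolysis genes rose in 1 and fell in 4 of 21 cases, with Aldoc at -2.86 (SE 0.45), and did not pass as a list (adjusted p = 0.15). Against WT number 1 alone 15 ribosome biogenesis and 7 cytokine genes rose, while 5 naive and quiescent genes fell (median log2 fold change -0.68, from -0.88) and 7 glycolysis genes fell.

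CD28 Y170F was compared with WT to ask what the tyrosine motif contributes (n = 3 and 2). At day 1, 10 genes changed (3 higher and 7 lower), 486 passed an unadjusted p of 0.05, and 6 changed against WT number 1 alone. Acadl, encoding an acyl-CoA dehydrogenase of fatty acid oxidation, fell from 44.7 ± 4.67 to 16.6 ± 3.1 CPM (log2 fold change -1.43, SE 0.17, adjusted p = 2.9e-05). Ly6c1 was at -1.61 (SE 0.31, adjusted p = 0.038). It was called lower at day 1 in every other mutant too, with log2 fold changes of -1.4 to -2.1. All share the same WT libraries, at 55.4 ± 26.6 CPM, so a difference of those libraries is not separated from genotype. At day 3, 5 genes changed (2 higher and 3 lower), 935 passed an unadjusted p of 0.05, and 8 changed against WT number 1 alone. With RLE size factors the day 3 count was 4, of which 1 was higher and 3 lower. Acadl was again lower at day 3 (-1.22, SE 0.16, adjusted p = 3.8e-04). The remaining genes named here were chosen after their values were seen. Eda2r held 3534 counts over the 3 libraries at day 1 and 3016 at day 3, against 0 and 2 counts in WT. The noncoding gene 6820402A03Rik held 0 counts at day 1 against 147 in WT. At day 1, 6 of the 10 changed genes lay within 15 Mb of Cd28, as did 4 of the 5 at day 3, against 223 of all 18292 genes (one-sided Fisher's exact p = 6.2e-10 and 1.1e-07). Fisher's exact test takes genes as independent units, although Acadl and 6820402A03Rik both lie 6.1 Mb from Cd28. All 6 day 1 genes near Cd28 also changed with the same sign in CD28 AYAA.

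In CD28 Y170F no glycolysis gene of 21 changed on either day by edgeR. As a list they were lower at day 3 (median log2 fold change -0.54, adjusted p = 3.3e-10, and adjusted p = 0.74 with an estimated correlation), with a median of -1.02 against WT number 1 alone. CD28 Y170F library 1 decided the day 3 count, since without it 1159 genes changed (317 higher and 842 lower). Pkm stood at 1500 CPM in that library and at 613 and 505 CPM in the other 2, against 1780 and 819 CPM in WT. DESeq2 called 25 genes at day 1 and 11 at day 3, and a fit to these groups alone called 2 and 0, the latter by edgeR with 273 at an unadjusted p under 0.05.

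**Figure D2:**
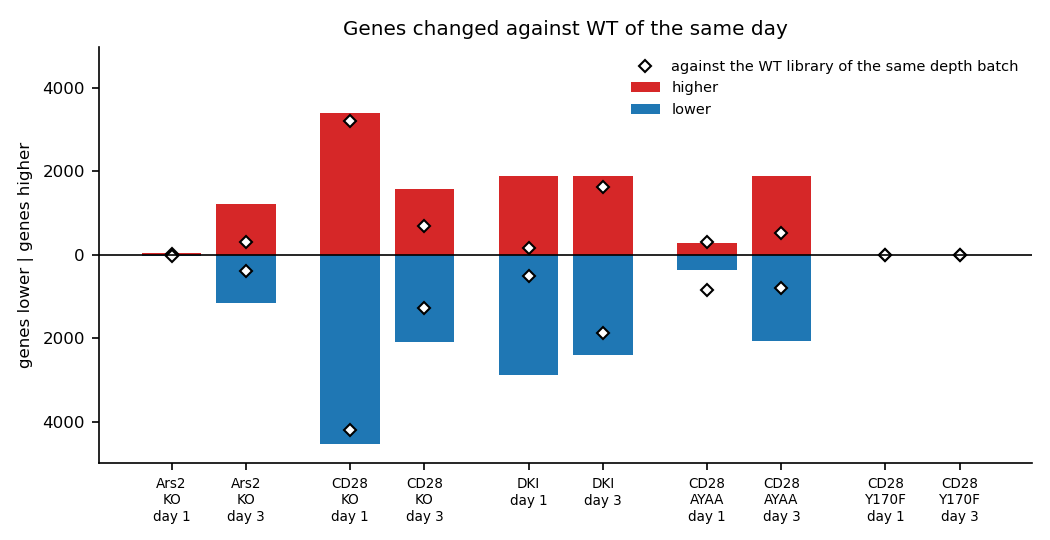
Number of genes higher (red, upward) and lower (blue, downward) than in WT of the same day for each genotype, with diamonds for the numbers against the WT library of the same depth batch. At day 1 the bars run from 10 genes in CD28 Y170F to 7922 in libraries labelled CD28 KO.

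**Figure D3:**
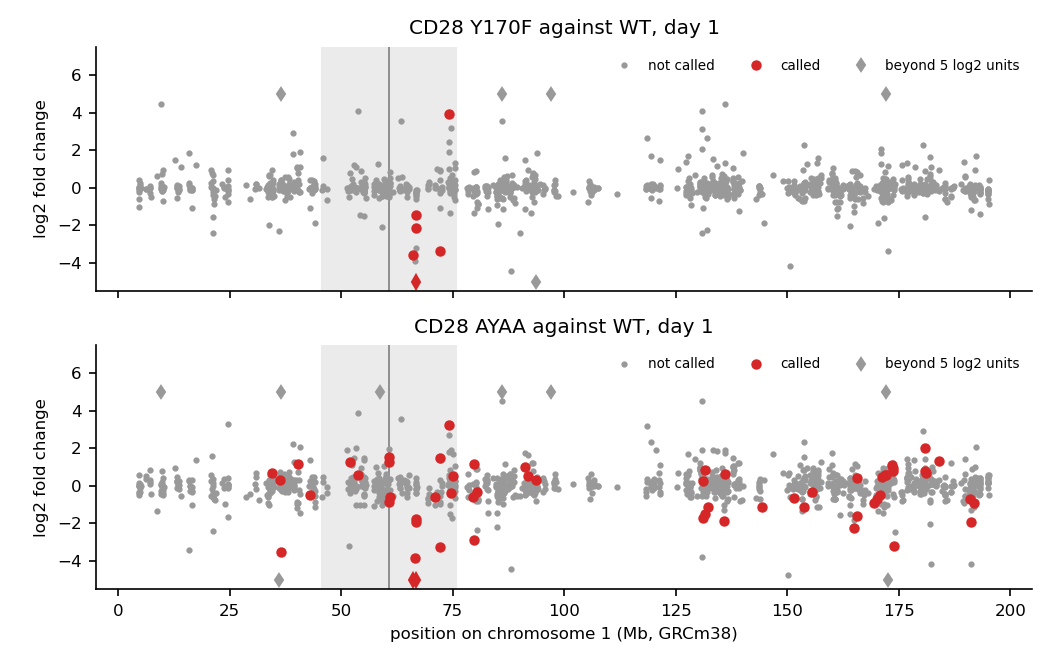
Log2 fold change against WT at day 1 for tested genes along chromosome 1 (position in Mb, GRCm38), with called genes in red, Cd28 at the vertical line and the 15 Mb on either side shaded. In CD28 Y170F all 6 called genes of chromosome 1 lie in the shaded segment.

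DKI was compared with libraries labelled CD28 KO to ask what a mutant receptor retains (n = 3 and 2). These groups lie in different depth batches, so depth can be separated from genotype only through the WT libraries, which span both. At day 1, 1657 genes differed (1153 higher and 504 lower in DKI), 1811 with depth batch as a term, and 207 without CD28 KO number 1. Irf4, encoding a transcription factor of activated lymphocytes, held 546 ± 20.4 CPM in DKI and 56.5 ± 11.5 in libraries labelled CD28 KO (log2 fold change 3.27, SE 0.27, adjusted p = 2.3e-08). Lag3, encoding an inhibitory receptor, was higher by 3.57 (SE 0.42), and Ctse was at -4.9 (SE 0.21). Early activation genes were higher in 13 and lower in 1 of 26 cases, with 21 and 1 when adjusted over the list alone (adjusted p = 3.4e-16, and adjusted p = 0.0018 with an estimated correlation). Glycolysis genes were higher in 2 and lower in 0 of 21 cases, with 6 and 1 when adjusted over the list alone (adjusted p = 0.015, and adjusted p = 0.61 with an estimated correlation). B cell markers were lower in DKI in 9 of 15 cases and higher in 0. At day 3, 83 genes differed (40 higher and 43 lower), 250 by DESeq2, 30 with depth batch as a term, and 15 without the CD28 KO library in column 2. Gpr55 was higher (2.54, SE 0.33), and Ctse (-5.3, SE 0.21) and Ikzf2 (-1.73, SE 0.31) were lower. Gpr55, Ctse and Ikzf2 lie on chromosome 1, as Cd28 does, and Ikzf2 lies within 15 Mb of it. For them a strain variant linked to Cd28 was not separated from an effect of the receptor.

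CD28 AYAA and CD28 Y170F were compared directly to set the motifs of the receptor tail against each other (n = 3 and 3), within 1 depth batch. At day 1, 796 genes differed (397 higher and 399 lower in CD28 AYAA). The replicate numbers paired the samples at day 1, and with the number as a block 5878 genes differed (2734 higher and 3144 lower), 781 of the 796 among them. Lta held 28.4 ± 3.2 CPM in CD28 AYAA and 116 ± 10.8 in CD28 Y170F (log2 fold change -2.02, SE 0.32, adjusted p = 4.4e-04). Irf8 was at -1.92 (SE 0.24) and Ephx1 at 1.87 (SE 0.25). Cell cycle genes were lower in 12 and higher in 0 of 34 cases, 27 lower when adjusted over the list alone (adjusted p = 1.7e-17, and adjusted p = 0.2 with an estimated correlation). Early activation genes were lower in 9 and higher in 1 of 26 cases, with 15 and 2 when adjusted over the list alone (adjusted p = 2.0e-09, and adjusted p = 0.021 with an estimated correlation). No glycolysis gene of 21 passed by edgeR, while 14 were lower and 3 higher with the block. The glycolysis list gave adjusted p = 0.0065, adjusted p = 0.58 with an estimated correlation, and adjusted p = 1.2e-08 with the block. The stress response list passed with the block (adjusted p = 0.04) and not without it (adjusted p = 0.15). With both the block and an estimated correlation no list passed, at adjusted p = 0.31 for glycolysis, 0.49 for stress response and 0.19 for early activation. Without CD28 AYAA number 1 the count of genes was 185.

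At day 3, 6735 genes differed between CD28 AYAA and CD28 Y170F (3228 higher and 3507 lower in CD28 AYAA). Lif held 162 ± 2.7 CPM in CD28 AYAA and 4.91 ± 3.91 in CD28 Y170F (log2 fold change 5.03, SE 0.63, adjusted p = 1.7e-06). Lta was higher by 3.69 (SE 0.35) and Lrrc32 by 3.66 (SE 0.31), while Mxd4 (-2.83, SE 0.35) and Ctla4 (-2.51, SE 0.36) were lower. Ribosome biogenesis genes were higher in 26 and lower in 1 of 29 cases (adjusted p = 2.8e-23, and adjusted p = 0.24 with an estimated correlation). Naive and quiescent T cell genes were lower in 22 and higher in 0 of 23 cases, 22 and 1 when adjusted over the list alone (adjusted p = 7.1e-14, and adjusted p = 0.24 with an estimated correlation). Cytokine genes were higher in 8 and lower in 0 of 17 cases (adjusted p = 1.1e-05, and adjusted p = 0.011 with an estimated correlation).

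**Figure D4:**
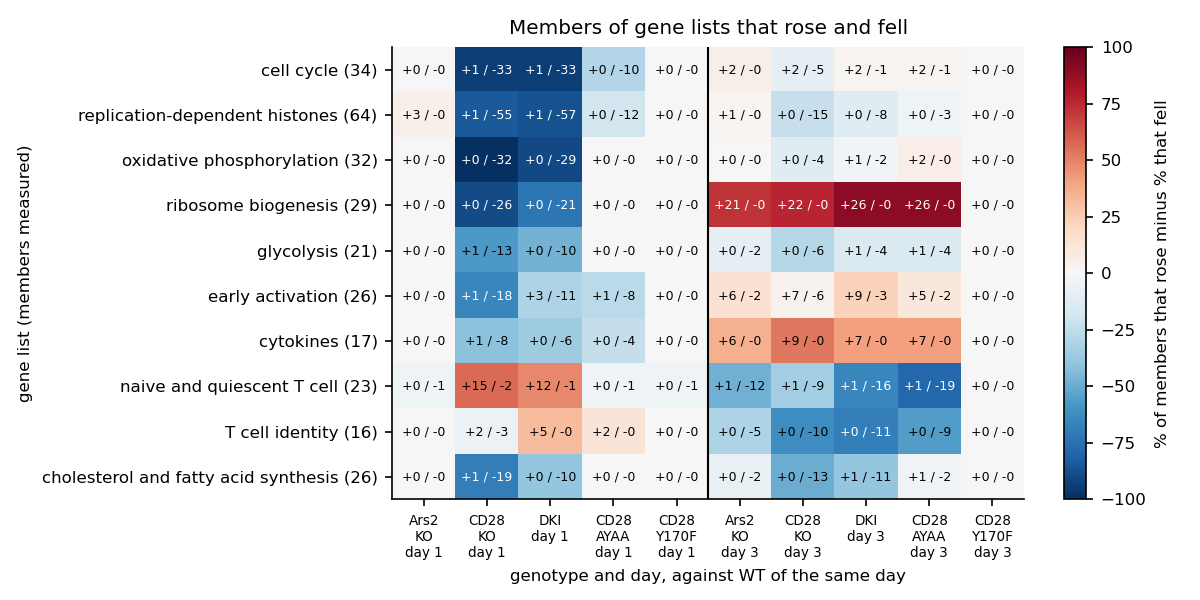
Members of 10 gene lists that rose and fell against WT of the same day, in each cell as numbers and by colour as the percentage that rose minus the percentage that fell. Ribosome biogenesis genes fell in libraries labelled CD28 KO and DKI at day 1 (26 and 21 of 29) and rose at day 3 in all genotypes but CD28 Y170F (21 to 26 of 29). Against the WT library of the same depth batch 26 and 0 fell at day 1 by edgeR, and at day 3 the genes that rose numbered 1 in Ars2 KO, 9 in libraries labelled CD28 KO, 26 in DKI and 15 in CD28 AYAA.

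Whether a genotype acts differently on the days was tested as an interaction, the fold change against WT at day 3 minus that at day 1. It passed for 673 genes in Ars2 KO (349 higher and 324 lower at day 3, and 170 with the replicate number as a block), 6455 in libraries labelled CD28 KO (3759 and 2696), 5938 in DKI (3241 and 2697) and 4455 in CD28 AYAA (2248 and 2207). In CD28 Y170F it passed for 0 genes by edgeR, 423 at an unadjusted p under 0.05, and 5 by DESeq2. Without WT number 4 at day 3 the count was 129 in Ars2 KO and 2147 in CD28 AYAA, and without WT number 1 at day 1 it was 3766 in DKI. Without Ars2 KO number 3 at day 3 the Ars2 KO count was 1993. Lif had an interaction of 8.59 (SE 1.1, adjusted p = 3.4e-06) in libraries labelled CD28 KO, 6.24 (SE 0.92) in DKI, 5.64 (SE 0.89) in CD28 AYAA and 3.49 (SE 0.85) in Ars2 KO. Lta gave 5.95 (SE 0.58), 5.95 (SE 0.54), 5.24 (SE 0.53) and 3.48 (SE 0.51) in the same order. Srrt in Ars2 KO gave 1.38 (SE 0.33, adjusted p = 0.021), and did not pass without WT number 1 at day 1 (0.82, adjusted p = 0.22) or without WT number 4 at day 3 (1.05, adjusted p = 0.18). Cd28 gave -1.58 (SE 0.25, adjusted p = 3.1e-05) in libraries labelled CD28 KO, -1.33 (SE 0.23) in DKI and -1.09 (SE 0.23) in CD28 AYAA.

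Ribosome biogenesis genes had a higher interaction in 14 of 29 cases in Ars2 KO (24 when adjusted over the list alone), 28 in libraries labelled CD28 KO, 27 in DKI and 27 in CD28 AYAA, and a lower one in 0. The tests gave adjusted p = 2.5e-21, 2.4e-23, 8.2e-24 and 1.8e-25, and adjusted p = 0.15, 0.18, 0.17 and 0.18 with an estimated correlation. Cell cycle genes had a higher interaction in 31 of 34 cases in libraries labelled CD28 KO and 32 in DKI, against 12 in CD28 AYAA and 1 in Ars2 KO. In Ars2 KO the cell cycle list did not pass (adjusted p = 0.31). The other tests gave adjusted p = 2.4e-20, 8.1e-22 and 5.6e-07, and adjusted p = 0.2, 0.17 and 0.54 with an estimated correlation.

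The effect of Ars2 KO was set beside that of each CD28 allele to ask whether loss of Srrt resembles loss of CD28 signalling. Correlations are across 18292 genes, which are not independent replicates, and all share the same WT libraries. At day 1 Pearson's r was 0.28 with libraries labelled CD28 KO, 0.20 with DKI, 0.46 with CD28 AYAA and 0.51 with CD28 Y170F. Groups simulated without any effect against the shared controls gave means of 0.54, 0.35, 0.61 and 0.61. At day 3 the values were 0.64, 0.64, 0.72 and 0.25, against simulated means of 0.63, 0.36, 0.67 and 0.65. The covariance exceeded the simulated one at day 3 by 0.172 for libraries labelled CD28 KO, 0.215 for DKI and 0.174 for CD28 AYAA. It was lower than the simulated one for CD28 Y170F, with a difference of -0.0344, and at day 1 the differences were 0.0471, 0.0129, 0.0291 and 0.00788. Among genes with a mean log2 CPM of at least 3 the day 1 correlations fell to 0.16, 0.06 and 0.34 for the first 3 alleles, and the day 3 value for CD28 Y170F became -0.07.

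At day 3, 751 genes were higher in both Ars2 KO and libraries labelled CD28 KO, 822 in both Ars2 KO and DKI, and 864 in both Ars2 KO and CD28 AYAA. Independent lists would share 103.5, 123.9 and 125. The shared lower genes numbered 745, 844 and 816, against 131.3, 150.5 and 129.8, and 9, 3 and 3 genes went in opposite directions. In all 4 of these genotypes together, 652 genes were higher and 644 lower at day 3, Lta, Lif and Lrrc32 being among the higher ones and Ly6c1 among the lower ones. Without WT number 4 at day 3 these fell to 134 and 209, and the pairs shared 170, 172 and 158 higher and 258, 294 and 247 lower genes. Without WT number 1 the 4 genotypes shared 621 and 489. The 2 WT libraries per day are too few to split, so part of the excess may come from the shared controls.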

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

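The interactions were planned and the test of uncalled genes near Cd28 was chosen before its result was seen, while the other tests of explanations in this part, and the 15 Mb window around Cd28, were chosen after the results they address were seen. The effect of a genotype against WT differed between day 1 and day 3, by a test of that difference, for 673 genes in Ars2 KO (170 with the replicate number as a block), 6455 in libraries labelled CD28 KO, 5938 in DKI and 4455 in CD28 AYAA. Of the targeted genes, Srrt had a day 3 minus day 1 difference of 1.38 in Ars2 KO. Cd28 had differences of -1.58 in libraries labelled CD28 KO, -1.33 in DKI and -1.09 in CD28 AYAA.

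In libraries labelled CD28 KO, DKI and CD28 AYAA, some genes of cell cycle (33, 33 and 10 of 34) and early activation (18, 11 and 8 of 26) were lower than WT at day 1, and some of ribosome biogenesis (22, 26 and 26 of 29) and cytokines (9, 7 and 7 of 17) were higher at day 3. With an estimated correlation the cell cycle and ribosome biogenesis lists did not pass in any of the 3, with adjusted p = 0.14, 0.059 and 0.24 for cell cycle and 0.52, 0.24 and 0.23 for ribosome biogenesis. A sex difference is argued against as the whole cause, because all DKI and stimulated WT libraries are male, and because at least 88.9% of the called genes of each list stayed called in each genotype with sex as a term. Depth batch as a term moved the counts of changed genes at day 1 from 4765 to 1522 in DKI and from 661 to 2248 in CD28 AYAA. It left called at least 93.9% of the cell cycle genes and 81.8% of the early activation genes lower at day 1, and at least 81.8% of the ribosome biogenesis genes and 85.7% of the cytokine genes higher at day 3, in each genotype. The batch term rests only on WT number 4 against WT number 1, so it cannot tell batch from a difference between these samples. Against the WT library of the same batch every median log2 fold change kept its sign. At day 1 the medians were -3.01, -1.38 (from -2) and -1.16 for cell cycle and -1.53, -0.56 and -0.6 for early activation. At day 3 they were 0.77, 1.73 and 0.97 for ribosome biogenesis and 1.63, 2.22 and 1.62 for cytokines. With 1 WT library each, this argues against batch as the whole cause for the medians only. Against the WT library of the same batch, ribosome biogenesis genes that stayed called at day 3 in libraries labelled CD28 KO were 9 of 22, where the median log2 fold change went from 1.07 (median SE 0.26) to 0.77 (median SE 0.31), a smaller change with a wider error. Cytokine genes there were 4 of 9, with medians of 1.76 (median SE 0.81) and 1.63 (median SE 0.96), so a part played by WT number 4 at day 3 stays open. A candidate explanation is slower progress along the response, which would give fold changes that run against the change from day 0 to day 1 at day 1 and against that from day 1 to day 3 at day 3. The day 1 axis was CD28 Y170F at day 1 minus unstimulated WT, and the day 3 axis CD28 Y170F at day 3 minus day 1. The correlations were -0.29, -0.10 and -0.13 at day 1 and -0.57, -0.59 and -0.53 at day 3. The highest of them, -0.1, misses the -0.3 set for all 6, so slower progress stays open at day 1. Ars2 KO, where 0 cell cycle and 0 early activation genes were lower at day 1, gave -0.26 at day 1 and -0.4 at day 3. A more negative day 1 value than in DKI or CD28 AYAA thus came without that loss. Against day 0, 5 cell cycle genes rose and 14 fell in DKI at day 1, and 0 histone genes rose and 57 fell. Slower progress alone would not put genes below day 0, but the unstimulated libraries also differ in markers of other cells.

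Of the few genes called in CD28 Y170F, 6 of 10 at day 1 and 4 of 5 at day 3 lay near Cd28 on chromosome 1. Eda2r on chromosome X was called on both days and lies outside any segment linked to Cd28. The share near Cd28 restates the pattern, so genes that were not called on the day in question were tested instead. Of those within 15 Mb of Cd28, 13 of 217 (6%) had an unadjusted p under 0.05 at day 1 against 2.6% elsewhere, and 18 of 219 (8.2%) at day 3 against 5%. The larger of both one-sided Fisher's exact p values was 0.031, and values under 0.05 on both days were predicted for a strain variant linked to the edited gene. However, Map2, Cxcr2 and Gm38218, called at day 1, stayed in the day 3 set. Their day 3 log2 fold changes were -3.44 (SE 0.73), 3.48 (SE 0.91) and -1.66 (SE 0.39). Gm25360, called at day 3, stayed in the day 1 set. The tests are therefore not separate from the pattern, and a strain variant stays open. Library batch or a single WT library is argued against as the whole cause, because 3 of the 6 near-Cd28 genes called at day 1 stayed called without either WT library and with depth batch as a term. Loss of signalling through the mutated tyrosine, seen from CD28 AYAA, whose motif leaves that tyrosine in place, is argued against too, because 4 of the 6 genes were called there with the same sign without either WT library and with depth batch as a term, while none was called with that sign by edgeR in Ars2 KO, which is compared with the same WT libraries. That argument covers only an effect particular to this tyrosine. A loss of signalling shared by both motifs would move the same genes in both alleles, and it stays open. The median ratio of DKI to CD28 Y170F fold changes over these genes was 0, which decides nothing about the mutated tyrosine while the changes that DKI carries are not stated.

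Srrt was less reduced in Ars2 KO at day 3 than at day 1. Low Srrt in WT number 4 is argued against as the source, since the log2 ratio differed by 1.49 between the days against WT number 1 alone and by 1.34 against WT number 4 alone. Outgrowth of cells that kept Srrt could give such a change, but the difference of 1.38 in counts of mixed cells cannot be told apart from recovery within cells. No count of edited cells is in these data.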

How the results depend on the processing

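Depth batch as a term, sex as a term and protein-coding genes alone were alternatives chosen after the data were seen, and the others were planned. RLE size factors and sex as a term moved no count of changed genes by more than 1.5 times, and no named or targeted gene that passed changed sign under any alternative. No list that passed changed direction with RLE size factors. The check with the estimated correlation reused the direction of the preset one, so it could not show a change of direction. Without WT number 4 the median of the histone list in Ars2 KO at day 1, which had passed, went from 0.47 to -0.07. Of the results below, the cause was not tested unless a sentence names it. DESeq2 called 206 genes in Ars2 KO at day 1, 1428 in CD28 AYAA at day 1, 25 and 11 in CD28 Y170F at days 1 and 3, 250 in DKI against CD28 KO at day 3, 1443 in CD28 AYAA against CD28 Y170F at day 1, 1302 for the Ars2 KO interaction and 5 for the CD28 Y170F interaction. limma-voom called 3 in CD28 Y170F at day 3, and 1012 and 50 in DKI against CD28 KO at days 1 and 3. With no filter on low counts the numbers were 137 in Ars2 KO at day 1, 1338 in CD28 AYAA at day 1, 26 and 17 in CD28 Y170F at days 1 and 3, 268 in DKI against CD28 KO at day 3 and 1282 in CD28 AYAA against CD28 Y170F at day 1. A fit to only the groups compared has fewer samples to estimate the spread. It called 4 and 0 genes in Ars2 KO at days 1 and 3, and 2254 in libraries labelled CD28 KO at day 3. In CD28 Y170F it called 2 and 0 at days 1 and 3. The number of samples alone does not account for the 0 in Ars2 KO. DKI has as many libraries, and the same fit called 5072 and 4195 genes there at days 1 and 3. Between replicates at day 3 the mean chi-square was 34.2 to 90.4 in Ars2 KO and 2.38 to 5.54 in DKI, whose depth was lower. By edgeR the 2 counts of 0 stand beside 2382 and 273 genes at an unadjusted p under 0.05, and beside 2739 and 11 by DESeq2 on all libraries. With depth batch as a term the numbers were 5007 in DKI at day 1 against day 0, 1455 in Ars2 KO at day 3, 1522 in DKI at day 1, 2248 and 2376 in CD28 AYAA at days 1 and 3, 6 in CD28 Y170F at day 1, and 30 in DKI against CD28 KO at day 3. With protein-coding genes only, 4 and 2 genes were called in CD28 Y170F at days 1 and 3, since the others are noncoding or lost by the smaller set. With the estimated inter-gene correlation 45 of 868 list tests passed, against 450. Among genes with a mean log2 CPM of at least 3, the similarity of Ars2 KO at day 1 was 0.16 with libraries labelled CD28 KO, 0.06 with DKI and 0.34 with CD28 AYAA. At day 3 it was 0.78, 0.8 and 0.86 in that order, and reversed to -0.07 with CD28 Y170F.

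Without 1 library at a time, which leaves some groups with a lone library assumed to vary like the other groups, counts against day 0 stayed within 1.5 times. The lowest and highest counts against WT were 28 (without Ars2 KO number 1) and 201 (without WT number 1) in Ars2 KO at day 1, and 700 (without WT number 4) and 3581 (without Ars2 KO number 3) at day 3. In libraries labelled CD28 KO they were 4868 (without WT number 1) and 7423 at day 1, and 1752 (without column 2) and 2641 at day 3. In DKI they were 671 (without WT number 1) and 4908 at day 1, and 2132 (without WT number 4) and 3535 at day 3. In CD28 AYAA they were 67 (without WT number 1) and 1146 (without WT number 4) at day 1, and 1316 (without WT number 4) and 3634 at day 3. In CD28 Y170F they were 6 (without number 1) and 25 (without WT number 1) at day 1, and 4 (without number 2) and 1159 (without number 1) at day 3. DKI against CD28 KO gave 207 (without CD28 KO number 1) and 1043 (without DKI number 2) at day 1, and 15 (without CD28 KO column 2) and 50 (without DKI number 3) at day 3. CD28 AYAA against CD28 Y170F gave 185 (without CD28 AYAA number 1) and 410 (without CD28 AYAA number 3) at day 1. The interactions ranged from 129 to 1993 in Ars2 KO (without WT number 4 and Ars2 KO number 3 at day 3), 3766 to 6014 in DKI (without WT number 1 at day 1 and at day 3), 2147 to 4681 in CD28 AYAA (without WT number 4 and number 1 at day 3) and 0 to 2 in CD28 Y170F (the latter without WT number 1 at day 1). The similarity of Ars2 KO at day 1 ranged over 0.16 to 0.45 with libraries labelled CD28 KO, 0.09 to 0.47 with DKI, 0.37 to 0.67 with CD28 AYAA and 0.42 to 0.75 with CD28 Y170F. At day 3 it ranged over 0.58 to 0.76, 0.57 to 0.76, 0.64 to 0.83 and 0.12 to 0.57 in that order.

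With the replicate block, which also restricts the fit to the groups compared, CD28 AYAA against CD28 Y170F gave 5878 genes at day 1 and 2311 at day 3, where the same groups without the block gave 3502 and 4113. At the preset correlation the block changed no list call at day 1 but that of the stress response list. At the estimated correlation it ended the calls of early activation (adjusted p = 0.021 to 0.19), cytokines (0.027 to 0.31) and regulatory T cell genes (0.016 to 0.31). The block called 170 genes for the Ars2 KO interaction. WT samples of 1 number also share a depth batch on both days, and in none of the mutants listed next did every number correlate between the days by more than 0.1. Samples of 1 number correlated between the days at 0.55 in WT (2 pairs), 0.25, 0.18 and -0.15 in Ars2 KO, -0.06, 0.07 and 0.02 in DKI, 0.36, 0.06 and 0.36 in CD28 AYAA, and -0.21, -0.01 and -0.04 in CD28 Y170F. It called 5709 genes for the DKI interaction and 4111 for that of CD28 AYAA. Mutants could not be paired with WT, because they share fewer than 2 numbers with WT, and because the columns of CD28 KO at day 3 carry other numbers than its samples. The 6 libraries of CD28 AYAA and CD28 Y170F allow 10 splits, too few for a share under 0.05. In each case 1 of the 10 splits, the real one, gave as many genes, with 796 at day 1 against at most 0 in another split, and 6735 at day 3 against at most 1483. The depth of the 8 libraries under 12 M counts limits genes of low expression in DKI and in WT number 4.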

Other observations

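Of the tests in this part, that of noncoding genes in Ars2 KO was chosen after its result was seen, and the rule that sorts genes as noncoding was changed after a previous version had given a result. ARS2 takes part in the turnover of noncoding RNA, so a hypothesis was that such genes make up more of those raised in Ars2 KO at day 1. They were 11 of 42 raised genes (26.2%) and 0 of 31 lowered genes, against 16.4% of tested genes, and the one-sided Fisher's exact p of 0.072 left open a loss of RNA turnover that involves ARS2. At day 3 they were 102 of 1207 raised genes (8.5%) and 94 of 1146 lowered genes (8.2%), below the share of tested genes, so no such excess was seen on that day. A shared shift against these WT libraries stayed open as well. The share among raised genes was 6.8% in CD28 AYAA, 18% in libraries labelled CD28 KO and 15.6% in DKI, and the largest of the 3 one-sided Fisher's exact p values against Ars2 KO was 0.12.

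The genes called near Cd28 in CD28 Y170F were followed in the other genotypes, as genes chosen after their values were seen. The noncoding gene 6820402A03Rik had 0 counts at day 1 in CD28 Y170F, CD28 AYAA and libraries labelled CD28 KO, but 194 counts in DKI and 147 in WT. Gm25939 had day 1 log2 fold changes of -3.36 in CD28 Y170F, -3.26 in CD28 AYAA, -3.78 in libraries labelled CD28 KO and -0.7 in DKI, the last with adjusted p = 0.054. Acadl stood at -1.74 in CD28 AYAA, -2.77 in libraries labelled CD28 KO and -0.39 in DKI, the last with adjusted p = 0.089. Genes within 15 Mb of Cd28 made up 17 of 661 changed genes in CD28 AYAA at day 1 (one-sided Fisher's exact p = 0.0031), 106 of 7922 in libraries labelled CD28 KO (p = 0.11) and 58 of 4765 in DKI (p = 0.53). Among genes changed at least 4-fold they were 5 of 54 (one-sided Fisher's exact p = 5.0e-04), 22 of 1050 (p = 0.0094) and 5 of 403 (p = 0.55) in that order.

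Summed levels of 15 B cell markers at day 3 were 764, 960 and 871 CPM in CD28 Y170F against 636 and 619 in WT, but 196 to 216 in DKI, 233 to 258 in CD28 AYAA, 217 and 260 in libraries labelled CD28 KO, and 216, 173 and 542 in Ars2 KO. Most of each sum was Ighm, chosen after its values were seen, with 604 and 589 CPM in WT and 176 to 197 in DKI. The other 14 markers summed to 32.2 and 30.1 CPM in WT, 39.7 to 83.2 in CD28 Y170F, 17.1 to 20 in DKI, 17.4 to 40.6 in CD28 AYAA, 28.1 and 72.8 in libraries labelled CD28 KO and 15.7 to 32.9 in Ars2 KO. The sums therefore follow 1 gene, and no cause of its change was tested. Summed levels of 8 NK cell markers at day 3 were 107 and 94.5 CPM in libraries labelled CD28 KO, 47.5 to 54.8 in DKI, 44.6 to 136 in CD28 AYAA and 53.1 to 144 in Ars2 KO, against 28.5 and 34.3 in WT. The 4 CD4 lineage genes summed to 82.3 and 89.7 CPM in libraries labelled CD28 KO, 102 to 116 in DKI, 77.8 to 146 in CD28 AYAA and 92.8 to 295 in Ars2 KO, against 158 and 195 in WT. As lists, only NK cell markers in libraries labelled CD28 KO passed among these (adjusted p = 0.012, and adjusted p = 0.62 with an estimated correlation). The 4 CD8 lineage genes summed to 912, 808 and 680 CPM at day 3 in Ars2 KO against 1040 in each WT library. Their sums were 1020 and 948 CPM in libraries labelled CD28 KO, 1120 to 1220 in DKI and 1020 to 1170 in CD28 AYAA. A different mix of cells therefore stays open beside the day 3 changes.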
